A study of Homo sapiens with 6 samples.

How the data were processed

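Total RNA from HEK 293 cells transfected with control siRNA (3 samples) or RBM10 siRNA (3 samples) was labelled with Cy3 after oligo(dT) priming and read on 1-colour Agilent gene expression arrays, 1 array per sample, per the labels' protocols. The deposited files are scanner output made with Agilent Feature Extraction (version 11.5 in the submitters' processing notes). Per the file headers, the processed signal is a spot intensity that was background-subtracted and detrended within the array, with surrogate values for the dimmest spots and no scaling between arrays. The deposited flags for spots well above background, saturated spots and outlier spots are other columns of those files, per the file headers. The sequence and number of the siRNAs are not given in the sources used here.

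Each array held 62976 spots, of which 4259 control spots were left out, and the remaining 58717 spots carried 50599 probes of 60 bases, 902 of them printed 10 times. Probe coordinates are those of the files, on hg19. Of the probes, 28174 were named through their accession in a RefSeq table of the GRCh38.p14 assembly used only for names, 364 through a name shared with such a probe, and 22061 kept the name in the files. Medians of the processed intensity were 16.1 to 18.1 and 75th percentiles 312 to 359 per array. On RBM10 siRNA replicate 3 the detection limit from the spike-in RNAs was outside the range that Feature Extraction accepts.

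Signals were log2 transformed and the 75th percentile of each array was subtracted. Spots with an outlier flag for non-uniformity or population were dropped, and spots of 1 probe were averaged. Probes were kept when well above background on all arrays of at least 1 group, with at least 2 values per group, which left 24860. The brightest probe stood for each gene, giving 18867 genes. Of 26 named genes with several probes, 19 had all of them on the same side of 0, and 1, RBM10, had probes past the threshold on both sides. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package (1.17.8) for reading files and matplotlib 3.10.9 for figures. P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and a fold change of 2 was applied after the test. Folds are 2 to the power of the absolute log2 fold change, and SEs are on the log2 scale.

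A gene whose probe was not well above background on any array of 1 group has only a bound. The mean of the bright group was set against the mean over the dim group's arrays of the higher of the probe's own value and the lowest value well above background on that array. This applied to 169 of the genes called. For PPDPFL and TSKS, dim on 2 arrays of 1 group, the fold is also given with each array at the higher of those 2 values.

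The gene lists of the report were fixed before the data were examined, as were the limma and camera tests and the rule for named genes. Some tests of explanations and the gene families were chosen later, as stated beside them. That rule took RBM10, RBM5, RBM6, TUT1, NUMB, HMOX1, NQO1, ACTB and GAPDH, then the 8 largest increases and 8 largest decreases among genes past the threshold whose groups did not overlap, leaving out systematic names, then up to 4 members per list with the smallest adjusted p. Not every gene that the rule takes is reported here. Lists with at least 5 measured members were tested with camera on moderated t values with a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes. Fry tests whether a list's own genes move one way on balance. With an estimated correlation 0 of the 9 list calls held. For the interferon and cholesterol lists the estimate (-0.0052 and 0.0052) lay below the preset 0.01. Their unadjusted camera p values still rose, from 0.00217 to 0.0213 and from 0.00782 to 0.0471. Correlation among members alone therefore does not account for the loss of those calls. For the other lists called the estimate lay above the preset, and how much of their loss comes from correlation was not tested. A call lost under this setting is therefore not by itself evidence of correlated members.

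Alternatives covered normalization (normexp with an offset of 50 and quantile, quantile, median centring, 75th percentile of detected probes), filters, outlier flags, the probe rule, variance models, array weights, the replicate number or slide row as a block, and leaving out each array. Others were added after seeing the data, namely removal of trends with the base content of probes, scaling on spike-in spots, and slide row 1 alone. Slide positions were read from the arrays' identifiers.

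Data were simulated with the means and limma's moderated variances of the 18867 genes, and 200 genes were changed. Moderated variances are drawn towards a common value, so they spread less than the genes' own. Limma recovered 2% of the 50 genes changed by 0.25 on the log2 scale and 50% of those changed by 0.5. It recovered 76% of those changed by 1 and 100% of those changed by 2. Unchanged genes called numbered 9, or 7.3% of all calls. With no gene changed limma called 0 genes and camera called 0 lists. Genes were drawn independently, so the simulation cannot show how camera fares where list members are correlated. Far fewer genes were changed than the 9089 called in the data, so the recovery rates need not hold there.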

Results

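Total RNA was profiled from HEK 293 cells, a human embryonic kidney line, 48 h after transfection with a control siRNA or with siRNA against RBM10, an X-linked RNA-binding protein that regulates alternative splicing. Each group held 3 arrays, which the series design describes as independent experiments. Every sample was labelled with 1 dye and hybridised to its own array, from 500 ng of RNA. All 6 arrays lay on 1 slide and were scanned on 1 day, with the control arrays and RBM10 siRNA replicate 1 in slide row 1 and RBM10 siRNA replicates 2 and 3 in row 2. Of 58717 spots for genes on each array, 53.5% to 56.0% were well above background and 0 were saturated. The number of arrays limits the precision of every value below. Correlations between arrays, across genes, were 0.995 to 0.998 within a group and 0.986 to 0.988 between groups, and the first principal component, which separated the groups, held 68.4% of the variance. On the second component (12.7%) RBM10 siRNA replicate 1 lay at -28.6 and replicates 2 and 3, in row 2, at 14.6 and 10.5. Control arrays lay between -4.3 and 6.2 on it.

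RBM10 itself, the siRNA target, was measured first as a check of the labels. On its brighter probe (A_23_P125815, for NM_005676, at chromosome X from 47045914 to 47045973 on hg19), the log2 signal relative to the array's 75th percentile was 4.87 ± 0.04 (SD, n = 3) in control arrays and 3.89 ± 0.07 (SD, n = 3) after RBM10 siRNA. RBM10 transcript was at 50.7% of the control level, a log2 fold change of -0.98 (SE 0.06, limma adjusted p = 0.000249). It was lower on all 3 RBM10 siRNA arrays than on any control array, and an exact two-sided permutation test gave p = 0.10, the smallest that 3 arrays against 3 can give. The second probe named for RBM10 (A_33_P3499102, for AK098115, at chromosome X from 47037204 to 47037263) was dimmer and moved the other way, to 122% of control (log2 fold change 0.29, SE 0.08, limma adjusted p = 0.0279 over all probes). Averaging both probes gave a log2 fold change of -0.35 in place of -0.98. The exon or intron that holds each probe was not analysed here.

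**Figure D1:**
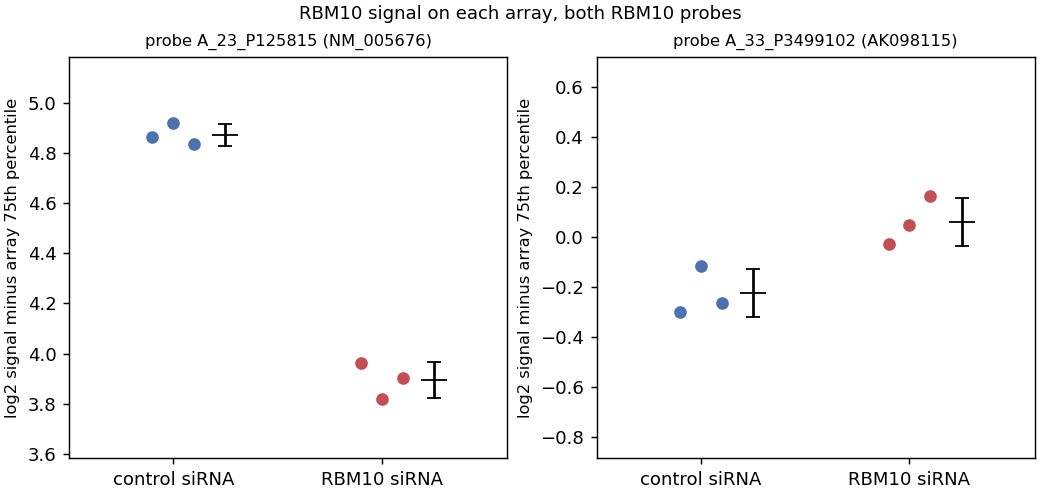
Each point is 1 array, with the log2 signal relative to that array's 75th percentile on the y axis and the group on the x axis, and the bars are the mean and SD of 3 arrays. The brighter probe lay at 4.87 in control and 3.89 after RBM10 siRNA, while the dimmer probe lay at -0.23 and 0.06.

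The comparison asked which transcripts differ in level when RBM10 is reduced. After RBM10 siRNA, 9089 of 18867 genes tested passed the threshold (limma, adjusted p under 0.05), of which 5008 were higher and 4081 lower. Most changes were small, with a median absolute log2 fold change of 0.46 among the genes that passed, and 815 genes changed at least 2-fold, 247 of them higher and 568 lower (225 with normexp and quantile normalization, and 602 to 933 under the other normalizations, filters, models and leave-one-out settings). The 2 groups of arrays did not overlap for 11268 genes, 59.7% of those tested, where chance gives 10%. The split of directions depended on the scaling, since 55.1% of called genes were higher in the main analysis, 39.2% when arrays were scaled on probes detected on all arrays and 67.2% when they were scaled on the spike-in spots. Row 2 held no control array. With slide row as a block, as within row 1 alone, the contrast is therefore RBM10 siRNA replicate 1 against 3 control arrays. Calls under these settings rest on 1 RBM10 siRNA array.

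**Figure D2:**
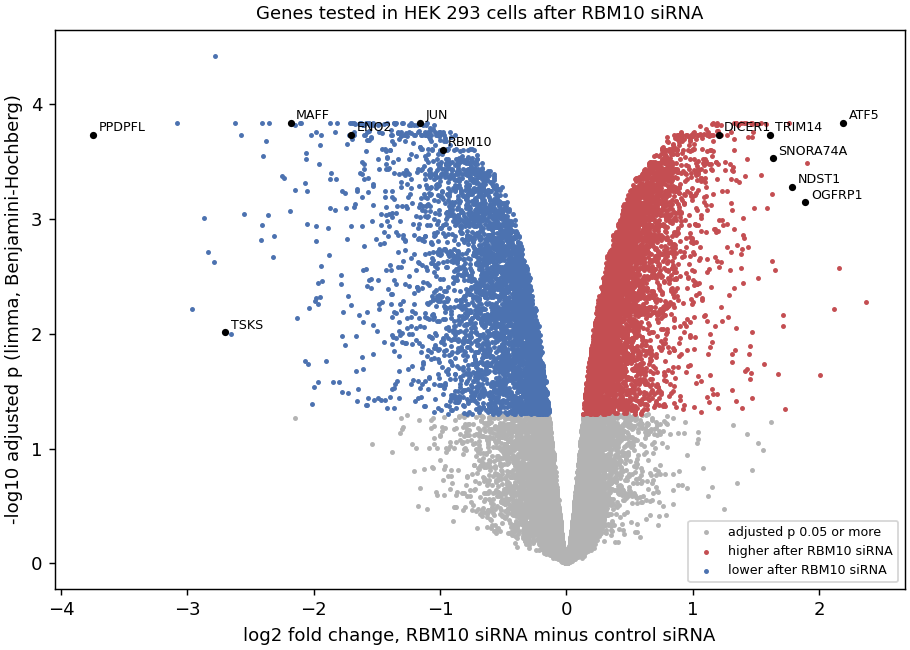
Each point is 1 of 18867 genes, with the log2 fold change (RBM10 siRNA minus control siRNA) on the x axis and the -log10 adjusted p from limma on the y axis. The 5008 genes higher and 4081 lower are coloured, named genes are black points, and genes near background in 1 group are plotted at their fitted values.

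The largest increase among named genes well above background was in ATF5, a stress-responsive transcription factor, which rose 4.56-fold (log2 fold change 2.19, SE 0.07, adjusted p = 0.000145). OGFRP1, a pseudogene, rose 3.71-fold, NDST1, an enzyme of heparan sulphate synthesis, 3.46-fold, and MARK2P9 3.09-fold. The probe for SNORA74A, a small nucleolar RNA, read 3.11-fold higher on RNA primed with oligo(dT). Whether that probe read the mature RNA or a longer transcript was not tested. TRIM14 rose 3.05-fold on its brightest probe, with log2 fold changes of 1.47, 0.63 and 0.13 on its others, of which the last did not pass. SIGLEC6 and ZNF287 were not well above background on any control array and were at least 1.58-fold and at least 1.73-fold higher after RBM10 siRNA. Their adjusted p values were 0.0230 and 0.0450. SIGLEC6 no longer passed without control replicate 2 or 3 or RBM10 siRNA replicate 2 or 3 (fitted log2 fold changes 1.85, 1.56, 1.88 and 1.98), nor ZNF287 without control replicate 1 or 2 or any 1 RBM10 siRNA replicate (1.74, 1.22, 1.97, 1.42 and 1.80). PPDPFL fell a fitted 13.4-fold (log2 fold change -3.74, SE 0.19, adjusted p = 0.000184) with 1 of 3 RBM10 siRNA arrays well above background, and 11.4-fold with dim values raised to the lowest value well above background. Its second probe had a log2 fold change of -2.97. TSKS fell a fitted 6.49-fold, also with 1 such array, and 4.21-fold with dim values raised. LINC01018, a long noncoding RNA, fell 6.29-fold on 2 arrays per group. The probe for LINC01018 holds a run of Cs, a feature whose signal also varied among control arrays, as do those for TNNI3 and KRT7 below. Other genes fell to a level not well above background on any RBM10 siRNA array, so only bounds apply. These were TCIM (at least 3.15-fold), SRCIN1 (at least 2.70-fold), SLC9B1 (at least 2.53-fold), NGFR, the low-affinity neurotrophin receptor (at least 1.98-fold), and LMOD1 (at least 1.98-fold), with adjusted p from 0.000145 to 0.00606.

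Most measured transcripts of splicing factors and of the RNA silencing machinery rose. Of 46 measured splicing factors of the SR, hnRNP and related families, 33 rose and 3 fell (34 and 3 adjusted over the list alone), with a median log2 fold change of 0.36 (camera adjusted p = 1.75e-06, but adjusted p = 0.261 with an estimated correlation). SRSF10, an SR protein, rose 1.83-fold on its brightest probe (SE 0.05 on the log2 scale), with log2 fold changes of 0.67 and 0.24 on its others. SRSF8 rose 1.81-fold, MBNL1, a regulator of alternative exons, 1.75-fold, and TRA2B 1.83-fold on its brightest probe, against log2 fold changes of 0.22 and -0.02 on its others. In the RNA silencing machinery, 13 of 15 genes rose and 1 fell (the same numbers adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.00139, but adjusted p = 0.261 with an estimated correlation). DICER1, which cuts microRNA precursors, rose 2.31-fold (log2 fold change 1.21, SE 0.06), AGO1 1.58-fold (log2 fold change 0.28 on its second probe) and TNRC6B 1.43-fold. XPO5, the exporter of those precursors, rose 2.36-fold on its brightest probe, while 2 other probes had log2 fold changes of 0.10 and 0.14 that did not pass.

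Cleavage and polyadenylation factors moved both ways, with 12 of 23 higher and 4 lower (12 and 5 adjusted over the list alone), a median of 0.20 and a camera adjusted p of 0.157. PCF11 rose 1.78-fold, CPSF6 1.59-fold and CSTF3 by 0.58 on the log2 scale, and WDR33 fell 1.79-fold on its brightest probe, with log2 fold changes of -1.18, -0.78, -0.35 and 0.76 on its others, of which the last 2 did not pass. CSTF3 had a second probe at -0.16, and its mean over probes of 0.21 did not pass. Among 6 measured relatives and partners of RBM10, 3 rose and 2 fell, RBM10 included (3 and 2 adjusted over the list alone), and the camera adjusted p was 0.711, with a median of 0.18 and a mean of -0.06. U2SURP, a spliceosome protein, rose 1.37-fold (log2 fold change 0.46, SE 0.06, adjusted p = 0.00191) and RBM5, the closest paralog of RBM10, 1.19-fold (adjusted p = 0.00781). RBM5 did not pass under either quantile normalization (log2 fold changes 0.13 and 0.09). RBM6 was 1.26-fold higher (adjusted p = 0.0276), NUMB, a Notch regulator whose exon choice RBM10 controls, 1.18-fold higher (adjusted p = 0.0201), and TUT1, a nuclear poly(A) polymerase, 1.45-fold lower (adjusted p = 0.0183). RBM6 no longer passed without control replicate 1 or 3 or RBM10 siRNA replicate 2 or 3 (log2 fold changes 0.31, 0.27, 0.33 and 0.32), nor TUT1 without the same arrays (-0.43, -0.49, -0.53 and -0.49). NUMB no longer passed without control replicate 2 or 3 or RBM10 siRNA replicate 2 or 3 (0.21, 0.22, 0.23 and 0.23) or under any of the other planned normalizations (0.14 to 0.20). With slide row as a block, which rests on RBM10 siRNA replicate 1 alone, log2 fold changes were 0.29 for RBM6, 0.21 for NUMB and -0.44 for TUT1.

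In the DNA replication list 29 of 48 members rose and 0 fell (29 and 0 adjusted over the list alone), with a median log2 fold change of 0.20 (camera adjusted p = 0.000216, but adjusted p = 0.261 with an estimated correlation). GINS1, a helicase component, rose 1.78-fold, RRM2, a ribonucleotide reductase subunit, 1.66-fold, E2F1, the S-phase transcription factor, 1.53-fold and CCNE1, or cyclin E, 1.45-fold. Of 54 replication-dependent histone transcripts, probed on RNA primed with oligo(dT), 20 rose and 0 fell (19 and 0 adjusted over the list alone). Their median was 0.16 (camera adjusted p = 0.00187, but adjusted p = 0.437 with an estimated correlation). H2AC12 rose 1.44-fold, H2AC4 1.43-fold and H2BC11 1.27-fold. These values cover only the forms of histone transcripts that oligo(dT) priming copies, so total histone mRNA was not measured. The mitosis list had 13 higher and 4 lower of 51 (10 and 4 adjusted over the list alone) and did not pass (camera adjusted p = 0.157). CCNB1, or cyclin B, rose 1.47-fold on its brightest probe, with a log2 fold change of 0.19 on the other that did not pass (adjusted p = 0.0542), and ANLN rose 1.43-fold.

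Of 31 measured genes of cholesterol and lipid synthesis 14 rose and 3 fell (16 and 4 adjusted over the list alone), with a median log2 fold change of 0.19 (camera adjusted p = 0.0235, but adjusted p = 0.261 with an estimated correlation). SCD rose 1.67-fold, ACAT2 1.59-fold and EBP, a sterol isomerase, 1.49-fold. The call for this list was lost under several other settings. With slide row as a block and in row 1 alone, both resting on 1 RBM10 siRNA array, its median was 0.15.

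In the glycolysis and hypoxia list 18 of 35 fell and 2 rose (the same numbers adjusted over the list alone), with a median log2 fold change of -0.21 (camera adjusted p = 0.00191, but adjusted p = 0.348 with an estimated correlation). ENO2, a glycolytic enzyme, fell 3.26-fold (log2 fold change -1.70, SE 0.09), NDRG1 3.04-fold, ANKRD37 3.03-fold and PFKFB4 1.92-fold, of which the last 3 are known hypoxia targets. Immediate early and AP-1 genes showed 13 of 34 lower and 3 higher (the same numbers adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.0154, but adjusted p = 0.348 with an estimated correlation). MAFF fell 4.54-fold (log2 fold change -2.18, SE 0.07, adjusted p = 0.000145), ATF3 2.52-fold on its brightest probe (log2 fold changes -1.36, -0.65 and 0.10 on its others, the last not past the threshold), JUN, a subunit of AP-1, 2.23-fold, and KLF10 1.59-fold. With slide row as a block, which rests on 1 RBM10 siRNA array, the median of this list was -0.14.

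**Figure D3:**
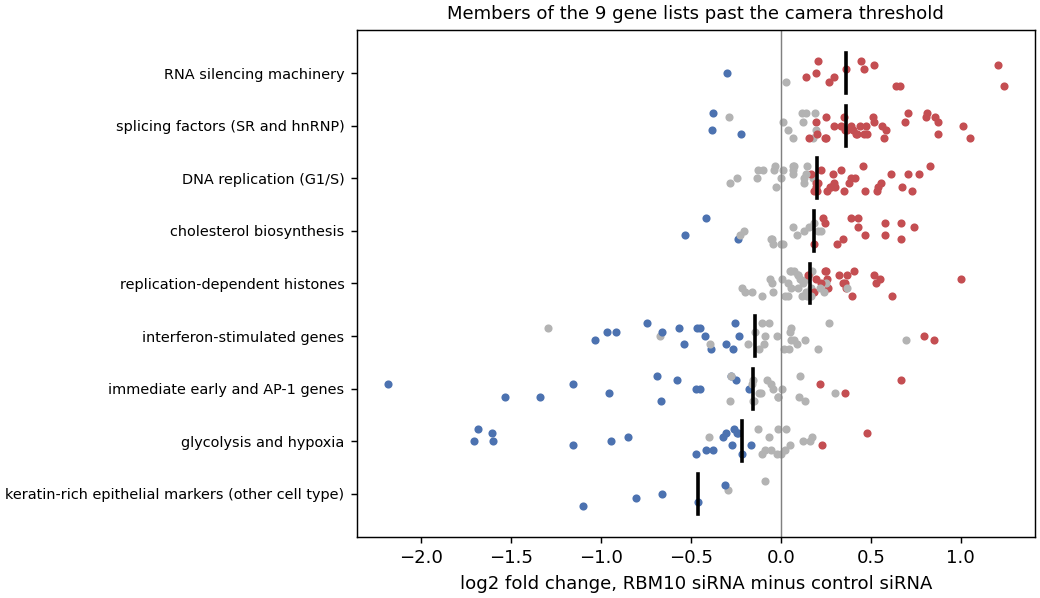
Each point is 1 measured member of the 9 lists past the camera threshold, with its log2 fold change (RBM10 siRNA minus control siRNA) on the x axis, coloured where it passed adjusted p 0.05, and the bar is the list's median. Medians ran from -0.46 for the epithelial markers to 0.36 for the RNA silencing machinery and the splicing factors.

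The list of ATF4 targets and unfolded protein response genes moved in both directions, with 17 of 38 higher and 10 lower (19 and 10 adjusted over the list alone). Its median was 0.14 and its mean -0.05, and it did not pass (camera adjusted p = 0.605). DDIT4, an inhibitor of mTORC1 signalling, fell 3.21-fold, CHAC1, which degrades glutathione, 2.98-fold, and DDIT3, or CHOP, 1.90-fold. Among interferon-stimulated genes 15 of 39 fell and 2 rose (the same numbers adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.00977, but adjusted p = 0.261 with an estimated correlation). DHX58, a cytosolic RNA sensor of the RIG-I family, fell 1.96-fold, the membrane proteins IFITM1 1.89-fold and IFITM3 1.67-fold, whereas IFIT5 rose 1.73-fold.

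Several lists linked to the known targets and roles of RBM10 did not pass camera. The oxidative stress, hypertrophy marker and negative regulator lists did pass by fry, which does not compare a list with other genes. With 1 probe per gene, exon choice was not measured. In the oxidative stress list 5 of 19 rose and 2 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.487). KEAP1, the inhibitor of NRF2, rose 1.69-fold and GCLC, which makes glutathione, 1.66-fold. HMOX1, a classical NRF2 target, had a log2 fold change of 0.03 (SE 0.19, adjusted p = 0.914). NQO1 was not tested, because its signal was not well above background on enough arrays. Cardiac hypertrophy markers divided into 5 higher and 5 lower of 18 (5 and 7 adjusted over the list alone, camera adjusted p = 0.25). ACTA1 rose 1.76-fold, TNNI3 fell 1.93-fold, and TNNC1 fell at least 1.69-fold. GATA4, a cardiac transcription factor, fell 2.24-fold on its brightest probe, while its 3 other probes had log2 fold changes from -0.13 to -0.02 that did not pass. Negative regulators of hypertrophy had 9 higher and 4 lower of 22 (9 and 5 adjusted over the list alone, camera adjusted p = 0.456), with HDAC4 up 1.83-fold and HDAC5 down 1.40-fold.

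For the Notch pathway 7 of 33 rose and 10 fell (the same numbers adjusted over the list alone, camera adjusted p = 0.225). The Notch target HES7 fell 2.15-fold and HES1 at least 1.77-fold, and PSEN2, a gamma-secretase subunit, rose 1.61-fold. BCL2 family and death receptor genes numbered 12 higher and 8 lower of 30 (13 and 8 adjusted over the list alone, camera adjusted p = 0.521). BCL2, which blocks apoptosis, fell 1.71-fold on its brightest probe and had a log2 fold change of 0.06 on the other. The pro-apoptotic PMAIP1 and BBC3 fell 1.53-fold and 1.31-fold. Among p53 targets 6 of 28 rose and 9 fell (7 and 10 adjusted over the list alone, camera adjusted p = 0.491), with a median of 0.01, a mean of -0.06 and a test direction of down. TP53I3 rose 1.81-fold and GADD45A fell 1.68-fold.

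Oxidative phosphorylation genes comprised 17 higher and 10 lower of 71 (16 and 9 adjusted over the list alone, camera adjusted p = 0.301), among them SDHD, up 1.76-fold. Of 77 cytosolic ribosomal protein genes 2 rose and 4 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.711), with a median of 0.00, a mean of 0.01 and a test direction of down. RPL27A rose 2.77-fold on its probe, whose mean log2 signal in control arrays was -1.02, the lowest of the list (next RPS3, 5.60). RPL3 fell 1.42-fold. Transcripts that are hosts of snoRNAs or sensitive to nonsense-mediated decay had 9 higher and 5 lower of 28 (the same numbers adjusted over the list alone, camera adjusted p = 0.576), including SNHG16, up 2.29-fold, and GADD45B, down 2.09-fold. TGF-beta and matrix genes had 8 higher and 9 lower of 33 (9 and 10 adjusted over the list alone, camera adjusted p = 0.419), with ZEB2 up 2.16-fold on its brightest probe (1.03 and -0.26 on the log2 scale on its others, the last not past the threshold) and TIMP2 down 1.47-fold. Genes next to RBM10 on the X chromosome had 2 higher and 2 lower of 15 (the same numbers adjusted over the list alone, camera adjusted p = 0.576), and CDK16 rose 2.02-fold while USP11 fell 1.39-fold.

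Markers of other cell types were followed as a measure of sample composition. Keratin-rich epithelial markers had 5 of 7 lower and 0 higher (the same numbers adjusted over the list alone), with a median log2 fold change of -0.46 (camera adjusted p = 0.0129, but adjusted p = 0.348 with an estimated correlation). CDH3 fell 2.15-fold, KRT7 1.75-fold and CLDN4 1.38-fold. When probes were not filtered on background, the median of this list was -0.09 and it did not pass (camera adjusted p = 0.144). Fibroblast markers had 2 higher and 3 lower of 6 (the same numbers adjusted over the list alone, camera adjusted p = 0.491), with ACTA2 down 2.04-fold. Blood cell markers had 0 higher and 3 lower of 9 (the same numbers adjusted over the list alone, camera adjusted p = 0.157), with HBG1 down 1.85-fold on its brightest probe (log2 fold change -1.53 on the other). Only 3 hepatocyte markers were measured, too few to test, of which APOA1 fell 2.19-fold and 2 did not pass.

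Housekeeping genes, often used as references, changed in both directions, with 5 of 17 higher and 5 lower (6 and 5 adjusted over the list alone, camera adjusted p = 0.927), a median of -0.05 and a mean of 0.10. ACTB rose 2.01-fold (log2 fold change 1.01, SE 0.06, adjusted p = 0.000223), and its second probe had a log2 fold change of 0.65. TFRC rose 2.11-fold and PGK1 fell 1.30-fold. GAPDH was 1.19-fold lower (log2 fold change -0.245, SE 0.06, limma adjusted p = 0.0230). The call was lost with spike-in scaling (log2 fold change -0.16). It was also lost without control replicate 1 (-0.25) or 2 (-0.20), or without RBM10 siRNA replicate 2 (-0.22) or 3 (-0.24). With slide row as a block, which rests on 1 RBM10 siRNA array, the log2 fold change of GAPDH was -0.19.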

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

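Spike-in scaling, removal of base content trends and row 1 alone were added after seeing the data. RBM10 stayed lower and past the threshold under all settings, with log2 fold changes from -1.09 to -0.35, and no named gene or list past the threshold reversed. Among all genes, 40 were called the other way with the mean over probes, 8 with outlier-flagged spots kept, 1 to 3 without single arrays and 1 with base content removed. Over 129 other genes named, 2559 of 2685 values kept their call, 123 lost it and 3 gained it. The count of genes called changed by over 1.5 times with slide row as a block (5784, with 3187 higher and 2597 lower). It did so too in row 1 alone (4036, with 2180 higher and 1856 lower). Under both settings RBM10 siRNA replicate 1 alone carries the contrast. Calls under them, these counts included, are therefore no check across the RBM10 siRNA arrays. Genes changed at least 2-fold numbered 225 with normexp and quantile and 815 in the main analysis. The normexp setting added an offset of 50, which shrinks the folds of dim probes. How much of the lower count comes from the offset was not tested. In a test against a 1.2-fold change (treat) 3413 genes passed. With base content removed 8645 genes passed. The median of all genes was 0.02 in the main analysis and 0.11 with spike-in scaling.

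Deviations from the group means gave no sign of pairing by replicate number, with correlations of -0.12, -0.08 and -0.00 for numbers 1, 2 and 3. Between unlike numbers they ran from -0.02 to 0.11. With so few arrays per group, pairing is not excluded. With a replicate block 7593 genes passed, RBM10 was at -0.98, 8 lists passed, and the cholesterol list did not (median 0.19).

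Lists past the threshold numbered 9, with 0 under an estimated correlation and 23 by fry. Medians of the lists lost under an estimated correlation were those of the main analysis, 0.36 for splicing factors and for RNA silencing, 0.20 for DNA replication, 0.16 for histones, 0.19 for cholesterol, -0.14 for interferon, -0.21 for glycolysis, -0.15 for immediate early genes and -0.46 for epithelial markers. The cholesterol list also lost its call with normexp and quantile (0.10), quantile (0.10), no filter (0.19), the mean over probes (0.18) and base content removed (0.15). Epithelial markers lost it without the filter (-0.088). With slide row as a block and in row 1 alone, both on 1 RBM10 siRNA array, the cholesterol median was 0.15. The median of immediate early genes was -0.14 with slide row as a block. Without the filter Notch (-0.15) and TGF-beta genes (-0.084) passed, and with spike-in scaling mitosis genes did (0.18). By fry, which does not compare a list with other genes, 14 more passed, namely polyadenylation factors (0.20), oxidative stress (0.090), hypertrophy markers (-0.23), negative regulators (0.12), Notch (-0.10), BCL2 family (0.13), p53 targets (0.0051), mitosis (0.086), oxidative phosphorylation (0.081), NMD and snoRNA hosts (0.016), TGF-beta (-0.12), fibroblast (-0.18), blood cell (-0.15) and housekeeping genes (-0.047). The cause was not tested in each case. Signal over background limits 169 called genes to a bound.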

Other observations

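Of the tests below, those on the slide row, on the base content of probes for the count of genes, on lower levels of transcripts with C runs and on background were chosen after the result was seen, as were the gene families and the genes named in them. Families were taken from gene symbols, with patterns tightened after a first look to leave out unlike genes. Of 25 families, 5 passed camera with the preset correlation and 0 with an estimated one. How much of that loss comes from correlation among family members was not tested. Mitochondrial ribosomal proteins, which translate the mitochondrial genome, had 48 of 76 genes higher and 1 lower, with a median log2 fold change of 0.25 (adjusted p = 1.36e-08, but adjusted p = 0.391 with an estimated correlation), and MRPL50 rose 2.23-fold and MRPL15 1.72-fold. Probes for snoRNAs, on RNA primed with oligo(dT), showed 87 of 205 higher and 13 lower, with a median of 0.25. Camera gave adjusted p = 0.000280, but adjusted p = 0.391 with an estimated correlation. Among them were the probes for SNORD56, up 2.71-fold, and SNORD69, up 1.88-fold. Whether these probes read mature snoRNAs or longer transcripts was not tested. Zinc finger genes had 171 of 410 higher and 55 lower (median 0.18, adjusted p = 0.00687, but adjusted p = 0.391 with an estimated correlation), including ZNF268, up 2.23-fold. Proteasome subunits had 21 of 37 higher and 3 lower (median 0.22, adjusted p = 0.0114, but adjusted p = 0.391 with an estimated correlation), and PSMD11 rose 1.66-fold. All of these also passed with base content removed.

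Collagens, the main fibrous matrix proteins, went the other way, with 14 of 29 lower and 3 higher, a median of -0.34 (adjusted p = 0.0154, but adjusted p = 0.403 with an estimated correlation) and COL6A2 down 2.13-fold. With base content removed their median was -0.24 (adjusted p = 0.0274). The antisense RNA DICER1-AS1 fell 2.68-fold where DICER1 rose 2.31-fold. Of 1456 genes with at least 2 probes past the threshold, 227 had probes past it in both directions.

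A large part of the genes tested was called, 9089 of 18867. Of the 10 splits of 6 arrays into 3 and 3, 1 gave as many genes, the real one, and the highest other count was 0. The same held for genes higher (5008, highest other 0), lower (4081, highest other 0) and changed at least 2-fold (815, highest other 0), and 1 split gave as many lists (9, highest other 7). These splits are too few for a share under 0.05. Each other split also mixes both treatments in each group. The treatment difference then adds to the spread within groups, so a count of 0 genes there is not what chance alone gives. Base content as the whole cause is argued against, since 8645 genes were called with base content trends removed. The slide row stays open. Row 1 holds only 1 RBM10 siRNA array, and with slide row as a block the contrast rests on the same array. Neither setting can therefore exclude an effect of the row. An effect of RBM10 reduction and an off-target effect of the siRNA both remain open, because the siRNA sequence was not used here.

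Probes with a C run (6 bases, all C but for the third or the fourth, which is any base, in 1568 probes well above background on all arrays) had a median log2 fold change of -0.13, against 0.06 for 19696 probes with neither a C run nor a G run and 0.03 for 1156 probes with a G run. Relative to probes with neither, the shift of C-run probes was 0.04 to 0.16 on control arrays, all in slide row 1. It was -0.03 on RBM10 siRNA replicate 1, also in row 1, and -0.16 and -0.14 on replicates 2 and 3, in row 2. The gap between the lowest control array and the highest RBM10 siRNA array was 0.073. Within 485 genes measured by both kinds of probe, the C-run probe lay below the others by a median of -0.085 (95% bootstrap interval -0.12 to -0.06). This is short of the -0.1 set in advance for an effect of the probe itself. Lower levels of C-rich transcripts and nothing else predicted an interval that includes no difference, which was not met. The interval resamples genes on the same 6 arrays, so it leaves out the spread between arrays. A probe effect and lower levels of C-rich transcripts cannot be told apart. An effect of the slide row stays open too, because row 2 held no control array. The probes of 1 gene can read different transcripts. For 61 of 568 genes at least 2-fold lower the probe held a C run (10.7%, against 8.0% of all genes), as it did for 10 of 247 genes at least 2-fold higher (4.05%). LINC01018 is one of the 61, and the probes for KRT7 and TNNI3, which fell less than 2-fold, also hold a C run. With base content removed these 3 had log2 fold changes of -2.36, -0.58 and -0.77 and passed.

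The 2 probes for RBM10 moved in opposite directions. Base content as the cause of the rise is argued against by a log2 fold change of 0.38 (SE 0.10, adjusted p = 0.0247) on the second probe with base content removed, against 0.29 (SE 0.08) before, and a signal near background by the probe being well above background on 6 of 6 arrays. A transcript that the siRNA leaves intact, or another RNA read by that probe, stays open and was not tested.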
